A study of Drosophila montana and Drosophila virilis with 24 samples.

How the data were processed

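The series comprises 24 one-colour (Cy3) arrays of a custom Agilent design, 1 for each pool of 10 female flies, with 600 ng of total RNA labelled per pool, per the labels' protocols. Spot intensities were deposited by the authors as scanner output of Agilent Feature Extraction 10.7.1.1, per the file headers; the processed signal is background-subtracted and detrended within an array and is not normalized between arrays. Flags for signal well above background, saturation and outlying spots were deposited in the same files. The authors also deposited a table of processed intensity values with 1850 rows on a linear scale, with column medians from 69.4 to 72.7. Its columns have nearly equal distributions, its normalization is not given in the sources used here, and limma is named in the submitters' processing notes without a role. Its rows carry numbers and no probe names, but their order is that of the scanner probes sorted by name: each column correlates at 0.9976 or more with its array's probe means in that order (0.0006 at most in file order), and 1767 of the 1850 rows lie nearest to the probe of their rank. Rows were therefore taken as probes in name order, for an alternative only.

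Each array held 15336 spots, of which 14800 were not controls: 1850 probes with 8 spots each. No spot was saturated, and 87 to 261 spots per array carried an outlier flag and were left out. The probes form 925 pairs in both orientations of the same fragment, 605 with paired names and 320 with array codes that share a fragment name. One orientation was usually far brighter (median gap 4.65 log2 units, and over 1 unit in 835 pairs), and 91.6% of the brighter and 63.8% of the dimmer probe values were well above background. The brighter probe of each pair, chosen over all 24 arrays without regard to groups, was taken as the gene's probe. The design had not foreseen probes of both strands, so this choice was made after the files were seen, and averaging both orientations was run as an alternative. Gene names are those inside the probe names, with spelling variants joined to D. melanogaster symbols by a hand-written table; 160 of 218 match symbols of the D. montana assembly ASM3504440v1, which was used for names only.

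Log2 processed signals were averaged over the spots of a probe, and each array's 75th percentile over non-control probes was subtracted. A gene's value is the mean over its probes that were well above background on all 3 arrays of at least 1 group of the fit, in each species for the comparison of species, which left 213 genes in D. montana, 211 in D. virilis and 209 in both. A gene had a median of 4 probes. Levels were not compared between species, since probes can match them unequally. An unequal match can also dampen a change, which the comparison of responses does not remove. Models were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, using the 15 D. montana arrays (5 groups), the 9 D. virilis arrays (3 groups) or all 24 arrays (8 groups) for differences between species. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. Replicates are separate pools of flies, per the labels. Tested on simulated data with 40 changed genes and 20 simulations, the procedure recovered 53.2% of changes of 0.5 log2 units and 94.0% of changes of 1 unit among 213 genes for D. montana acclimation, 85.0% and 99.0% among 211 genes for D. virilis acclimation, and 36.0% and 83.8% among 209 genes for the difference between species.

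Of 18 gene lists fixed before the data were examined, 12 had at least 3 measured members: heat shock and chaperone, cold response candidates, circadian clock, diapause and insulin signalling, carbohydrate and polyol metabolism, lipid metabolism, immune and humoral stress, vision, ion transport, courtship, cytoskeleton, and translation and reference genes. Lists for oogenesis, male germline, cuticle, storage proteins, ecdysone and oxidative stress had fewer and were not tested. Some genes belong to 2 lists. Lists were tested with fry, whose directional p asks whether members move one way on balance, and neither of its tests compares a list with other genes. Camera with an estimated correlation was an alternative; 13 of 108 list tests passed with fry and 0 with camera at an estimated correlation. Median, mean and test differed in sign in 13 of the 108, of which 2 passed and are named where they occur. Beside counts over all genes, counts are given adjusted over the list alone.

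Genes were named by a rule fixed in advance: for each comparison the 10 largest rises and 10 largest falls among genes past the threshold whose treated arrays all lay on the same side of the control arrays, the 2 smallest p-values of each list, hsr-omega, Hsp70, Hsp68, Hsp83, Fst, Inos, per, tim, vri, cpo, desat1, eIF-1A and Yp1 where measured, and the 5 smallest p-values where fewer than 5 genes passed. Hsp70, Inos, eIF-1A and Yp1 are not among the gene names used here. Chance puts 3 arrays entirely on 1 side of 3 others in 10% of orders; in D. montana acclimation 46.0% of genes were so separated.

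The arrays lay on 3 slides of 8, each with 1 array of every group. The main fits hold no slide term. Slide was fitted as a block as an alternative, and differences were also taken within each slide. Genes past the threshold were picked on these same arrays, so a shared direction on the 3 slides is largely fixed in advance. The replicate number equals the slide except for D. montana control replicates 2 and 3. Overlaps between comparisons were tested with Fisher's exact test (one-sided, adjusted over all overlaps), with 100 simulations of unchanged groups where controls were shared. Alternatives covered background correction (normexp with an offset of 50, on median signals because the mean signal column is not in these files), quantile and spike-in scaling (8 of 10 spike-in probes), the percentile over detected probes, filters on dim probes, the brightest probe per gene, the arrays fitted, replicate and slide blocks, array weights and leaving out each array. The authors' processed values, as log2 without further scaling, were another alternative. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.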

Results

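Whole-body gene expression was measured in mature females of 2 closely related flies, Drosophila montana and D. virilis, after several kinds of cold. Each array was hybridised with RNA from 1 pool of 10 flies that were 20 days old, and every group held 3 pools. Per the labels, all groups had 22 h of light and 2 h of darkness. The labels also give every group 1 time window, 5 to 6 h from lights on. Control flies stayed at 19°C. Cold-acclimated flies spent 14 days in control conditions and then 6 days at 5°C, and cold-hardened flies were kept at 0°C for 1 h. Chill coma is the reversible immobility of chilled insects. D. montana flies held at -6°C for 16 h were sampled after 15 min or 1 h of recovery, which gave 5 groups of D. montana and 3 of D. virilis, 24 arrays in all. The custom array carried 925 probe pairs for 218 named genes. Between 72.2% and 83.1% of spots per array were well above background, and the 75th percentile of the processed signal ran from 412.8 to 883.2 units. On the 6 recovery arrays it ran from 412.8 to 677.8, and on the others from 661.8 upwards. The number of arrays limits the precision of every value. Changes below are log2 fold changes ± SE with n = 3 arrays per group, and adjusted p-values are from limma with the Benjamini-Hochberg method. The SE rests on a spread shared over all arrays of the fit and moderated across genes. It can therefore understate the spread of the arrays compared, as for Adh in acclimated D. montana (SD of the arrays 0.87).

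The first comparison asked which genes responded to long, mild cold in D. montana. After acclimation, 57 of 213 genes changed, of which 21 were higher and 36 lower than in controls. The largest rise was in hsr-omega, a noncoding heat shock RNA gene (2.07 ± 0.18, 4.20-fold, adjusted p = 1.63e-07). It was followed by eyeless (ey), an eye-specifying transcription factor (1.70 ± 0.12, adjusted p = 1.99e-08), and by Hsp68, an inducible chaperone of the Hsp70 family (1.16 ± 0.15, adjusted p = 2.69e-05). The jetlag gene jet, which acts in light resetting of the clock, rose by 1.11 ± 0.13. Other risers were the co-chaperone gene stv (0.89 ± 0.13), amd (0.91 ± 0.31), knk (0.85 ± 0.25), the translational repressor gene Thor (0.84 ± 0.14), the eye transcription factor gene so (0.71 ± 0.14) and the small heat shock gene Hsp67Bc (0.67 ± 0.14). The 2 probes of Hsp67Bc disagreed, with log2 changes of -0.25 and 1.59. The largest falls were in the fatty acid desaturase gene desat1 (-1.86 ± 0.20, 3.63-fold lower, adjusted p = 2.29e-06), in Eip71CD, a methionine sulfoxide reductase gene (-1.80 ± 0.40), and in the alcohol dehydrogenase gene Adh (-1.72 ± 0.32). Pgm, CG12030, desat2, Treh, Arr2, p38a and cry completed the 10 largest falls, with log2 changes from -1.70 to -0.83.

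Members of both metabolic lists fell in acclimated D. montana. All 6 measured members of the carbohydrate list were lower: phosphoglucomutase (Pgm, -1.70 ± 0.12), trehalase (Treh, -0.94 ± 0.13), triose phosphate isomerase (Tpi, -0.62 ± 0.12), Adh, Gapdh1 (-0.38 ± 0.13) and Gapdh2 (-0.36 ± 0.13). Gapdh1 and Gapdh2 also had near-equal changes in acclimated D. virilis (-0.015 and -0.019). Whether their probes measure the 2 genes apart was not tested, so they may not count as 2 separate members. The count was also 6 adjusted over the list alone, and the list fell in fry's directional test (adjusted p = 2.31e-05, and adjusted p = 0.395 with an estimated correlation). Its mean change was -0.81, -1.15 and -0.91 on slides 1, 2 and 3, and with slide as a block the adjusted p was 5.80e-05. Of 9 lipid genes, 5 fell, also 5 adjusted over the list alone: desat1, desat2 (-1.53 ± 0.21), Cyt-b5-r (-0.83 ± 0.13), CG17928 (-0.68 ± 0.21) and CG9743 (-0.39 ± 0.14). For CG9743, 1 of the 4 probes carried the fall. The other 4 lipid genes did not pass, with changes from -0.39 to 0.10. The lipid list fell (adjusted p = 0.00204, and adjusted p = 0.642 with an estimated correlation), with slide means of -0.62, -0.65 and -0.56 and an adjusted p of 7.23e-05 with the slide block. With spike-in scaling the carbohydrate list kept its call (adjusted p = 0.0194) and the lipid list did not (adjusted p = 0.199).

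Among 18 heat shock and chaperone genes, 5 rose in acclimated D. montana and none fell, the same number adjusted over the list alone: hsr-omega, Hsp68, stv, Hsp67Bc and Hop (0.44 ± 0.14). The list rose (adjusted p = 0.0221, and adjusted p = 0.642 with an estimated correlation), its slide means were 0.37, 0.24 and 0.34, and the adjusted p was 0.0154 with the slide block and 0.199 with spike-in scaling. Of 5 cold response candidates, hsr-omega and stv rose while desat1 and Dca, a regucalcin-like gene (-0.82 ± 0.22), fell, 2 and 2 also adjusted over the list alone (directional test adjusted p = 0.153). The clock list of 18 genes held 3 higher and 2 lower genes, 3 and 2 adjusted over the list alone: per rose (0.67 ± 0.13), as did vri (0.95 ± 0.31) and jet, while tim (-0.42 ± 0.13) and the blue-light receptor gene cry (-0.83 ± 0.14) fell. The probes of per did not move alike, with changes from -0.06 to 1.18, and 1 of the 3 acclimated vri values lay within the range of the controls. Clock genes changed in both directions, and the directional test was not passed (adjusted p = 0.508). All groups share 1 time window, so a shift in daily timing could not be told apart from a change in level. Of 5 immune and stress genes, imd (-0.52 ± 0.13) and p38a (-0.85 ± 0.19) fell, 2 adjusted over the list alone. That list's test was passed towards lower values (adjusted p = 0.0262, and adjusted p = 0.919 with an estimated correlation), although its median was 0.00057, and with spike-in scaling the adjusted p was 0.806. Its slide means were -0.32, -0.23 and -0.16, and the blocked adjusted p was 0.0154.

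The remaining lists passed no directional test in acclimated D. montana, and except where given the counts were equal adjusted over the list alone. Vision genes held 2 falls among 16, in the arrestin gene Arr2 (-0.86 ± 0.18) and in Gbeta76C (-0.58 ± 0.18). Of 11 ion transport genes, the calcium channel gene cac (-0.80 ± 0.17), the potassium channel genes slo (-0.60 ± 0.18) and eag (-0.54 ± 0.19) fell, and the dynamin gene shi rose (0.49 ± 0.15). The courtship list of 20 genes held 2 rises and 4 falls, with fru at 0.55 ± 0.13 and the dopa decarboxylase gene Ddc at -0.77 ± 0.16. Thor was the member of the 6 diapause and insulin genes that passed. No cytoskeleton gene of 3 passed over all genes (1 lower adjusted over the list alone), and Gapdh1 was the 1 of 4 translation and reference genes to pass. Hsp83, Fst and cpo did not pass, with log2 changes from -0.15 to 0.50. All 57 changed genes had the same direction on the 3 slides, and with slide as a block 64 genes passed, 55 of them among the 57. The acclimated arrays had 76.6% to 80.7% of spots well above background, against 81.2% to 82.6% in D. montana controls. Their 75th percentile of the signal was 661.8 to 752.7, against 699.1 to 846.6. An effect of signal level on these calls was not tested. Of the 23 named genes that passed, amd, knk, tim and vri lost their calls without 1 or another of the 6 arrays. The other changed genes were not followed singly. The count was 34, 36 and 35 without control replicates 1, 2 and 3, 25 (52.0% higher against 36.8%) with spike-in scaling, 11 with normexp background correction and 95 with array weights.

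**Figure D1:**
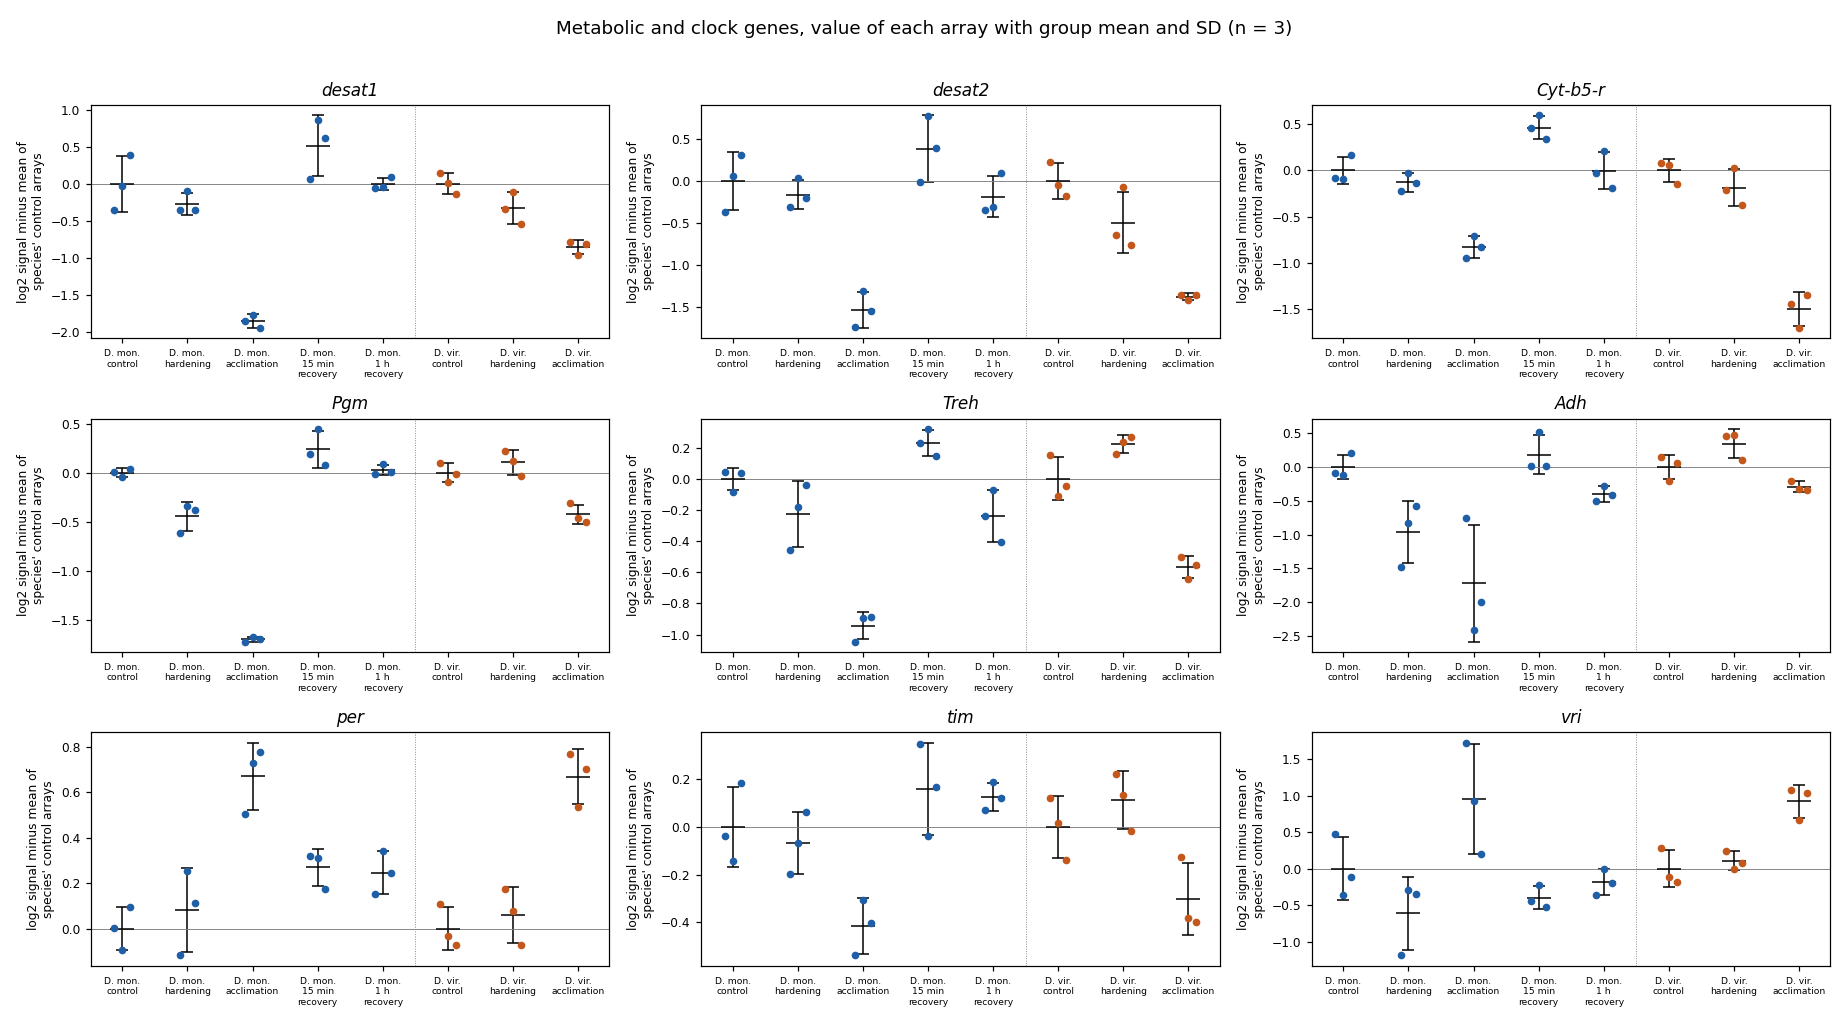
Log2 signal of 9 metabolic and clock genes (vertical axis, minus the mean of the same species' control arrays) for the 8 groups (horizontal axis); points are arrays, bars the mean and SD (n = 3), blue D. montana and orange D. virilis. After acclimation desat1 averaged -1.86 in D. montana and -0.85 in D. virilis.

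D. virilis was acclimated in the same way. Here 83 of 211 genes changed, 31 higher and 52 lower. Acclimation replicate 2 was the only 1 of the 24 arrays that Feature Extraction marked for evaluation, and it was kept. The highest rises were in CG6785 (2.99 ± 0.11, 7.92-fold, adjusted p = 3.21e-09), which rests on 1 probe, in hsr-omega (2.85 ± 0.08, 7.19-fold, adjusted p = 3.17e-10) and in black (b), an enzyme gene of beta-alanine synthesis (2.70 ± 0.30). Hsp67Bc (1.26 ± 0.10, its 2 probes at -0.10 and 2.62), ey (1.25 ± 0.10) and shi (1.20 ± 0.09) rose too. The ultraviolet opsin genes Rh3 and Rh4 rose by 1.11 ± 0.14 and 1.02 ± 0.16, Hsp20 by 1.03 ± 0.16 and vri by 0.93 ± 0.15. The lowest were Cyt-b5-r (-1.50 ± 0.13, 2.82-fold lower), desat2 (-1.37 ± 0.16), Eip71CD (-1.37 ± 0.16), amd (-1.23 ± 0.23) and the dopamine acetyltransferase gene Dat (-1.14 ± 0.14). Falls in desat1 (-0.85 ± 0.12), cac, ort, mnb and Caki followed, the last 4 between -0.78 and -0.62.

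Of 18 heat shock genes in acclimated D. virilis, 6 rose and 1 fell, the same adjusted over the list alone. The risers were hsr-omega, Hsp67Bc, stv (0.69 ± 0.09), the Hsp40 gene DnaJ-1 (0.60 ± 0.07), Hsc70-2 (0.60 ± 0.11) and l(2)efl (0.53 ± 0.13), and Hsc70-3 fell (-0.29 ± 0.09). The list was called higher (adjusted p = 0.00312, and adjusted p = 0.946 with an estimated correlation) although its median was -0.04 against a mean of 0.29. Its slide means were 0.35, 0.28 and 0.25, with an adjusted p of 0.0138 with the slide block and 0.246 with spike-in scaling. The 5 cold candidates were called higher (adjusted p = 0.000217, and adjusted p = 0.946 with an estimated correlation), with hsr-omega and stv higher and desat1 lower. Adjusted over the list alone, 3 rose and 1 fell, the slide means were 0.67, 0.73 and 0.60, and the blocked adjusted p was 0.00211. Lipid genes held 6 falls among 9, also 6 adjusted over the list alone, including CG9747 (-0.36 ± 0.09) and CG15531 (-0.32 ± 0.10). The lipid list fell (adjusted p = 0.00612, and adjusted p = 0.946 with an estimated correlation), with slide means of -0.58, -0.63 and -0.48, an adjusted p of 0.0263 with the slide block and of 0.126 with spike-in scaling.

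Of 6 carbohydrate genes in D. virilis, Treh (-0.57 ± 0.09) and Pgm (-0.42 ± 0.09) fell, and both did adjusted over the list alone. The clock list of 17 genes held 2 higher genes, per (0.67 ± 0.10) and vri, and 7 lower genes, among them cry (-0.52 ± 0.09), tim (-0.30 ± 0.11), slmb (-0.37 ± 0.08) and lark (-0.35 ± 0.08). Adjusted over the list alone, 3 rose and 7 fell, and the directional test was not passed (adjusted p = 0.411). The limit of 1 time window holds here too. As in D. montana, the per probes spread widely, from -0.05 to 1.25. The courtship list of 18 held 2 rises and 5 falls, the 8 ion transport genes 1 rise and 2 falls and the 5 immune genes 1 fall, imd (-0.35 ± 0.09), each with the same counts adjusted over the list alone. Vision genes held 2 rises, Rh3 and Rh4, and 1 fall among 16, with 2 rises and 0 falls adjusted over the list alone. Among diapause and insulin genes cpo (0.28 ± 0.09) and Ilp7 (0.27 ± 0.10) passed, but neither did adjusted over the list alone. Of 3 cytoskeleton genes muscle myosin (Mhc, 0.57 ± 0.12) rose and Act42A (-0.35 ± 0.10) fell, with 2 rises and 1 fall adjusted over the list alone, and 0 of 4 translation and reference genes passed either way. Hsp68, Hsp83 and Fst did not pass, with changes from -0.07 to 0.31. All 83 genes had 1 direction on the 3 slides, and 91 passed with slide as a block, 82 of them among the 83. With spike-in scaling 35 genes passed (68.6% higher against 37.3%) and with normexp 16 (62.5% higher). Of the 23 named genes that passed, cpo and tim lost their calls without 1 or another of the 6 arrays. Among these named genes Hsp67Bc, cac, ey, per and cpo turned in direction under 1 alternative or more. The other changed genes were not followed singly.

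The third question was whether the acclimation response differed between the species, tested as an interaction over 209 genes. It differed for 26 genes, 9 with the more positive response in D. montana and 17 with the more positive response in D. virilis. The names of 605 probe pairs begin with Dmon, for D. montana. Fragment names among the 320 array-coded pairs, as for per, begin so too, and the limit is not confined to the 605. A weaker match could dampen changes in D. virilis. For genes that changed less there, a probe effect cannot be told apart from a different response. CG6785 differed most (-2.45 ± 0.24 for D. montana minus D. virilis, adjusted p = 1.80e-07), with changes of 0.54 in D. montana and 2.99 in D. virilis. Hsp68 rose in D. montana, while its change in D. virilis was 0.03, a difference of 1.13 ± 0.19 (adjusted p = 0.000332). DnaJ-1 rose in D. virilis and stood at -0.0015 in D. montana, a difference of -0.60 ± 0.16 (adjusted p = 0.0174). Pgm fell further in D. montana (-1.27 ± 0.15, adjusted p = 2.04e-06), as did desat1 (-1.01 ± 0.25) and CG12030 (-1.02 ± 0.15), while Cyt-b5-r fell further in D. virilis (0.67 ± 0.18). The genes amd and Ddc passed in opposite directions in the 2 species: amd rose in D. montana and fell in D. virilis (difference 2.14 ± 0.43), and Ddc did the reverse (-1.04 ± 0.20). Of the 26 genes, 10 passed in both species, 11 in D. montana alone and 5 in D. virilis alone. The carbohydrate list was lower in D. montana relative to D. virilis (adjusted p = 0.00117, and adjusted p = 0.390 with an estimated correlation), with 3 members passing, 4 adjusted over the list alone. Its slide means were -0.55, -0.98 and -0.66, the blocked adjusted p was 0.000898, and with spike-in scaling it was 0.220. Of the 18 heat shock genes, 2 responses were more positive in D. montana and 3 in D. virilis (3 and 4 adjusted over the list alone), and of the 5 cold candidates 3 were more positive in D. virilis (also 3), without a passed directional test (adjusted p = 0.868 and 0.116). Of 8 ion transport genes 1 response was more positive in D. virilis (1 in D. montana and 2 in D. virilis adjusted over the list alone), and of 18 courtship genes 2 in D. montana and 1 in D. virilis (2 and 2). Of 16 vision genes 3, Arr2, Rh3 and Rh4, were more positive in D. virilis, of 9 lipid genes Cyt-b5-r was more positive in D. montana and desat1 in D. virilis, of 17 clock genes jet in D. montana and of 5 immune genes p38a in D. virilis, with equal counts adjusted over the list alone. No diapause and insulin, cytoskeleton or translation and reference gene passed either way. With slide as a block 29 genes passed, 26 of them shared, and 25 of the 26 had 1 direction on all 3 slides. Of the differences in the 20 genes named by rule, those of Adh, CG7182, Cyt-b5-r, Dat, Hop, Rh3, Rh4, fru and hsr-omega ended without 1 array or another. The count was 15 without D. montana control replicate 2, 4 with spike-in scaling (50% positive against 34.6%), 0 with normexp (45 genes had an unadjusted p under 0.05 in the main fit) and 56 with array weights.

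The acclimation calls of the species also overlapped. Of 210 genes tested in both, 13 were higher in both against 3.1 expected of independent lists (Fisher's exact test, one-sided, adjusted p = 1.32e-06), and 20 were lower in both against 8.67 (adjusted p = 3.31e-05). The 13 and 20 shared genes include hsr-omega, ey, so, stv, per, vri, knk and shi among the risers and desat1, desat2, Cyt-b5-r, Pgm, Treh, Eip71CD, cry and tim among the falls. Fold changes correlated across genes, which are not independent replicates (r = 0.63, rho = 0.56), and these comparisons share no arrays.

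**Figure D2:**
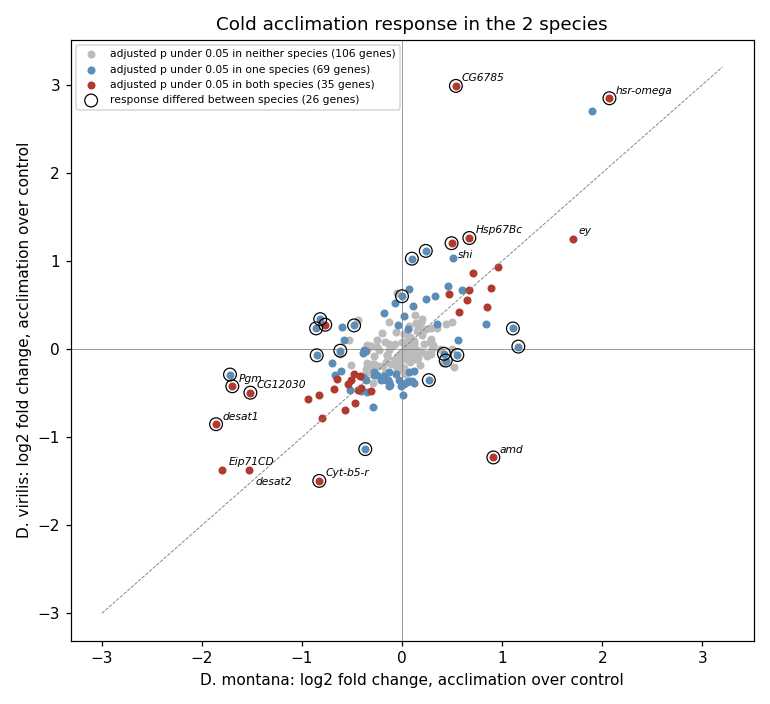
Log2 fold change of acclimation over control in D. montana (horizontal axis) and D. virilis (vertical axis) for each of 210 genes; colours mark genes past the threshold in neither, 1 or both species (106, 69 and 35 genes), rings the 26 genes whose response differed, and the dashed line equal change. hsr-omega lies at 2.07 and 2.85.

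Short hardening at 0°C changed 1 gene in each species. In D. montana it was Eip71CD (-2.17 ± 0.40, 4.49-fold lower, adjusted p = 0.0128), with the hardened arrays between -3.19 and -1.23 relative to the control mean. The next smallest p-values belonged to cwo (-0.70 ± 0.18), Pgm (-0.44 ± 0.12), hsr-omega (-0.63 ± 0.18) and Dr (-0.55 ± 0.17), with adjusted p from 0.136 to 0.183. In D. virilis the gene was ninaD, a carotenoid uptake receptor gene (0.68 ± 0.11, 1.61-fold, adjusted p = 0.0239). It was followed by b (1.41 ± 0.30), Dca (0.57 ± 0.13), sbb (-0.36 ± 0.10) and Hsp20 (0.54 ± 0.16), with adjusted p from 0.0698 to 0.240. No list passed its directional test in either species, and 0 list members passed over all genes in D. montana and 1, ninaD, in D. virilis. Adjusted over the list alone, Pgm and Adh (-0.97 ± 0.32) of 6 carbohydrate genes, cwo of 18 clock genes and hsr-omega of the 18 heat shock genes and of the 5 cold candidates were lower in D. montana, and Thor (0.43 ± 0.14) of 6 diapause and insulin genes was higher. In D. virilis Dca was higher and desat1 (-0.33 ± 0.12) lower among the 5 cold candidates, and ninaD was higher among 16 vision genes, while hsr-omega stood at -0.0022. The other 8 genes named in advance for D. montana lay between -0.61 and 0.25, and all 9 for D. virilis between -0.33 and 0.11. The hardening response differed between species for Eip71CD (-2.37 ± 0.51, adjusted p = 0.0253), which stood at 0.20 in D. virilis. The next smallest p-values of that test, all with adjusted p = 0.126, were those of Pgm (-0.55 ± 0.15), Adh (-1.31 ± 0.39), Thor (0.75 ± 0.23) and Dca (-0.92 ± 0.28). Adjusted over the list alone the difference passed for 3 carbohydrate genes (Pgm, Adh and Treh, -0.45 ± 0.16) and 2 cold candidates (Dca and hsr-omega), all more negative in D. montana, and for Thor, more positive there. At an unadjusted p under 0.05 there were 14 genes in D. montana, 22 in D. virilis and 32 for the difference. No gene passed in D. montana without control replicate 1 or 2 or hardening replicate 1 or 2, and 2 passed without hardening replicate 3. In D. virilis 0 passed without hardening replicate 1 or control replicate 2 or 3, and 7 without control replicate 1; the difference gave 0 to 3 genes. With slide as a block 1, 4 and 1 genes passed. All 3 single calls ended when only the compared groups were fitted, and all 3 ended with normexp.

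Recovery from chill coma was sampled in D. montana at 2 times. After 15 min, 14 of 213 genes differed from control, 5 higher and 9 lower. Eip71CD was lowest (-2.56 ± 0.40, 5.90-fold lower, adjusted p = 0.00199), followed by spin (-0.88 ± 0.23, 1 probe), the kinase gene mnb (-0.83 ± 0.16), the insulin receptor gene InR (-0.76 ± 0.18), and genes of membrane excitability: the calcium channel gene cac (-0.72 ± 0.17), the sodium channel auxiliary gene tipE (-0.65 ± 0.17) and the potassium leak channel gene Ork1 (-0.58 ± 0.14). CG14650 (-0.51 ± 0.13) and sbb (-0.46 ± 0.11, 5 of 6 probes lower) were lower as well. The higher genes were Hsp20 (0.79 ± 0.21), Thor (0.71 ± 0.14), the polyubiquitin gene Ubi-p63E (0.47 ± 0.12), Cyt-b5-r (0.46 ± 0.13) and CG12030 (0.45 ± 0.13). Of 11 ion transport genes, 2 passed, both lower, and 1 rose and 4 fell adjusted over the list alone; of 20 courtship genes 1 passed, lower, and 1 rose and 5 fell adjusted over the list alone; no list passed its directional test, that of the ion list reaching adjusted p = 0.0683. hsr-omega, Hsp68 and 7 other genes named in advance did not pass, with changes from -0.48 to 0.51. All 14 genes had 1 direction on the 3 slides, and with slide as a block 30 passed, including all 14. Every 15-min array was dimmer, with a 75th percentile of the signal of 480.8 to 677.8 against 699.1 to 846.6 in D. montana controls. An effect of signal level left after scaling could therefore not be told apart from the treatment. The count was 30, 1 and 4 without 15-min replicates 1, 2 and 3, 2, 6 and 5 without control replicates 1, 2 and 3, and 1 with spike-in scaling; of the 14 genes, 13 lost their call without 1 array or another, and Eip71CD kept it. The share of higher genes, 35.7%, was 16.7% with quantile normalization and 47.1% with the percentile over detected probes, and InR, cac and sbb turned in direction under 1 alternative or more.

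After 1 h of recovery 6 genes differed from control, 5 of them higher. hsr-omega rose by 1.63 ± 0.18 (adjusted p = 1.83e-05), Hsp68 by 1.26 ± 0.15 (2.39-fold, adjusted p = 2.26e-05), Thor by 1.21 ± 0.14 (adjusted p = 2.26e-05), stv by 1.03 ± 0.13 (adjusted p = 3.14e-05) and DnaJ-1 by 0.85 ± 0.14 (adjusted p = 0.000596). Eip71CD was 8.86-fold lower (-3.15 ± 0.40, adjusted p = 3.14e-05). Heat shock genes thus made up 4 of the 5 risers, among 18 measured (5 higher adjusted over the list alone, with Hsp26 at 0.48 ± 0.15). The list rose (adjusted p = 0.0306, and adjusted p = 0.535 with an estimated correlation), with slide means of 0.43, 0.30 and 0.09. Cold candidates (2 of 5 higher, 2 adjusted over the list alone, slide means 0.64, 0.34 and 0.45) and diapause and insulin genes (1 of 6, Thor, and 1 adjusted over the list alone, slide means 0.15, 0.25 and 0.11) had the same adjusted p-values of 0.0306 and 0.535. The 2 higher cold candidates, hsr-omega and stv, are also heat shock list members, so those 2 list results are not separate. The blocked adjusted p was 0.0211 for each of the 3 lists, and with spike-in scaling it was 0.696 for each. With quantile normalization the calls ended too, with adjusted p of 0.107, 0.0649 and 0.440. Of 4 translation and reference genes 0 passed, and 1 was higher adjusted over the list alone. The 7 other genes named in advance lay between -0.19 and 0.25. DnaJ-1 lost its call with spike-in scaling, and with normexp 2 genes passed. All 6 genes had 1 direction on the 3 slides, and all 6 were among the 14 that passed with slide as a block. The 1-hour arrays were also dimmer than every control array, with a 75th percentile of the signal of 412.8 to 583.3. Signal level and treatment could not be told apart here either.

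Comparing the times directly, 4 genes were higher at 1 h than at 15 min: hsr-omega (1.83 ± 0.18, adjusted p = 3.81e-06), Hsp68 (1.25 ± 0.15, adjusted p = 2.31e-05), DnaJ-1 (1.24 ± 0.14) and stv (0.82 ± 0.13, adjusted p = 0.000691). The next smallest p-value belonged to Treh (-0.47 ± 0.13, adjusted p = 0.0929), and Thor stood at 0.49 ± 0.14 (adjusted p = 0.0929). Adjusted over the list alone, Thor was higher and Treh and Cyt-b5-r (-0.47 ± 0.13) were lower at 1 h. All 4 were members of the heat shock list, which was higher at 1 h (4 of 18, also 4 adjusted over the list alone, adjusted p = 0.0494, and adjusted p = 0.366 with an estimated correlation). Its slide means were 0.43, 0.31 and 0.26, with an adjusted p of 0.0151 with the slide block and 0.660 with spike-in scaling. Cold candidates were also higher (2 of 5, with 2 higher and 1 lower adjusted over the list alone, adjusted p = 0.0494, and adjusted p = 0.570 with an estimated correlation), with slide means of 0.58, 0.17 and 0.34. That call ended with slide or replicate number as a block (adjusted p = 0.0514 and 0.0938). Its 2 higher genes, hsr-omega and stv, are also among the 4 of the heat shock list, so the 2 list results are not separate. The 7 other genes named in advance lay between -0.52 and 0.29. With spike-in scaling stv lost its call, and with normexp 1 gene passed. All 4 genes passed with slide as a block, where 5 did, and had 1 direction on the 3 slides.

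**Figure D3:**
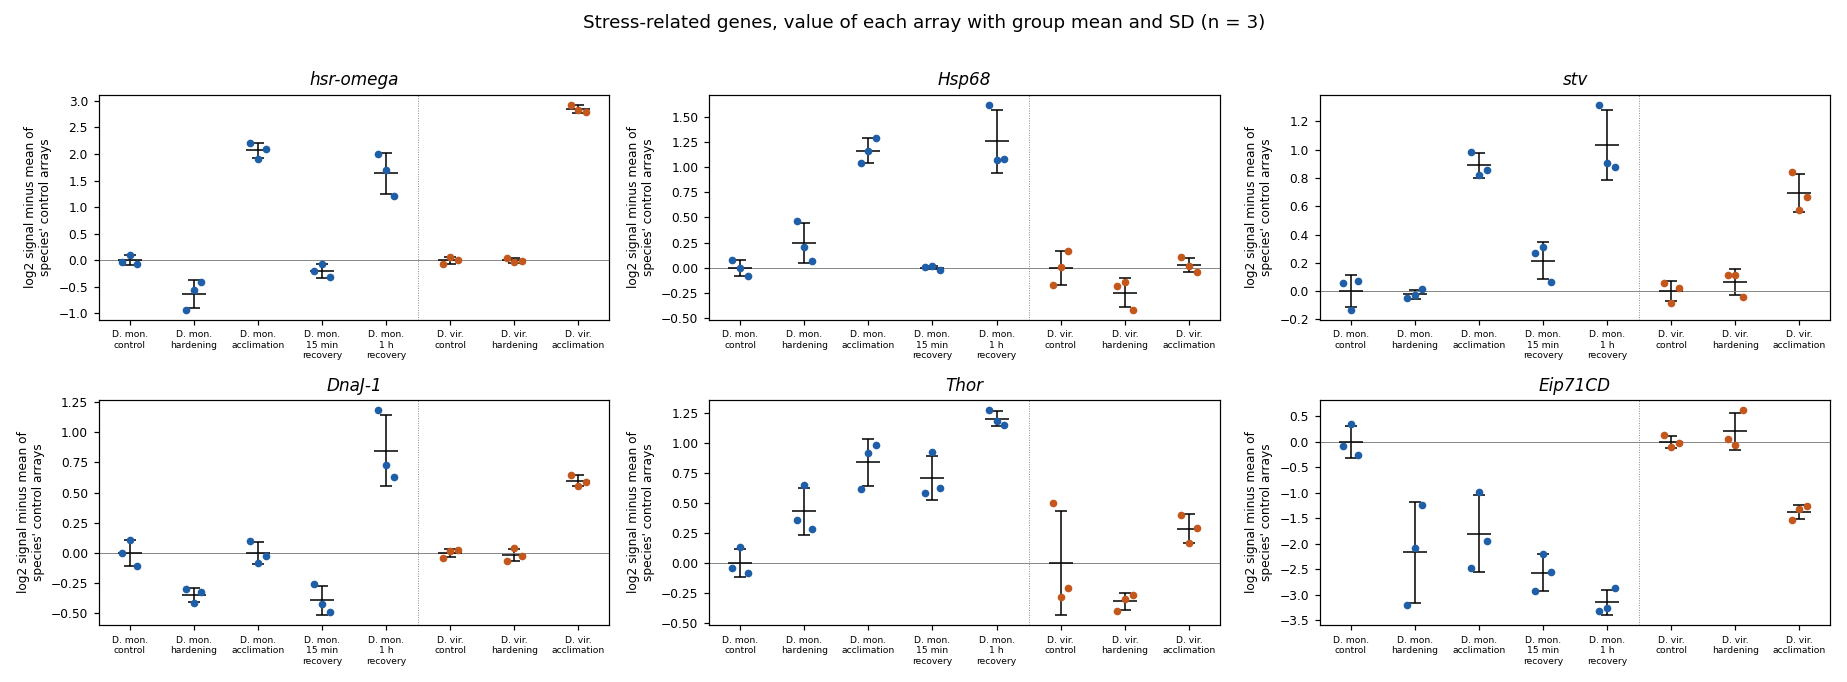
Log2 signal of 6 stress-related genes (vertical axis, minus the mean of the same species' control arrays) for the 8 groups (horizontal axis); points are arrays, bars the mean and SD (n = 3), blue D. montana and orange D. virilis. Hsp68 arrays lie between 1.04 and 1.29 in acclimated D. montana and between -0.04 and 0.11 in acclimated D. virilis.

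Calls of the D. montana treatments were set against each other. Acclimation and 1-hour recovery shared 4 higher genes, hsr-omega, Hsp68, stv and Thor, against 0.493 for independent lists (Fisher's exact test, one-sided, adjusted p = 0.00123), and 1 lower gene, Eip71CD, against 0.169 (adjusted p = 0.186). Unchanged groups simulated against the same controls shared 0 genes, which is no reference for these overlaps, since such groups gave 0 to 0.05 calls per comparison. The 2 recovery times shared 2 genes, Thor and Eip71CD, against 0.117 higher and 0.0423 lower genes for independent lists (adjusted p = 0.155 and 0.0730). Acclimation and 15-min recovery shared 5 genes in direction and 2 with opposite signs. Eip71CD was lower in all 4 D. montana treatments. Part of any excess may come from the 3 control arrays that these comparisons share.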

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

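The tests of the dimmer probes and the counts of other splits of the arrays were chosen after the results were seen. Differences between species are listed because the test of the difference itself passed. For acclimation, D. montana minus D. virilis in log2 units, the difference was negative for CG6785 (-2.45), Adh (-1.43), Pgm (-1.27), Dca (-1.16), Arr2 (-1.09), Ddc (-1.04), CG12030 (-1.02), desat1 (-1.01), Rh4 (-0.93), Rh3 (-0.88), p38a (-0.78), hsr-omega (-0.77), Dr (-0.75), shi (-0.71), DnaJ-1 (-0.60), Tpi (-0.60) and Hsp67Bc (-0.59). It was positive for amd (2.14), Hsp68 (1.13), jet (0.87), Dat (0.77), Cyt-b5-r (0.67), qtc (0.62), fru (0.62), Hop (0.57) and CG7182 (0.47). For hardening it was -2.37 for Eip71CD. Of 100 drawn splits of the 12 arrays, 10 gave as many genes as the 26 for acclimation (highest other 43) and 11 at least the 1 for hardening (highest other 2). Some of these splits keep or exchange the labels of a whole species and so carry its real response, which makes them no reference for the difference. With the mean response of both species first taken from the treated arrays, 1 of 100 splits, the real one, gave 26 genes for acclimation (highest other 2). Simulated arrays without any change gave 0.1 genes on average. Other splits can mix treated and control arrays that keep a real difference between species, which widens their spread and can lower their counts. This test was also chosen after the results were seen, so it does not exclude chance. For hardening 3 of 100 such splits gave at least the 1 gene, under the same limit, but another split gave 9, which points to a structure among those arrays, so the single gene is weak evidence.

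For the comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts were 57 and 0 for D. montana acclimation, 1 and 0 for hardening, 14 and 1 for 15-min recovery, 6 and 0 for 1-hour recovery, 83 and 0 for D. virilis acclimation, and 1 and 0 for its hardening. In each of these 1 split, the real one, reached the real count. For 1-hour against 15-min recovery the counts were 4 and 31, and 2 splits reached the real count. The split with 31 genes set 15-min replicate 1 and 1-hour replicates 1 and 2 against the rest, which points to a structure among the recovery arrays. These 3 arrays were the brightest of the 6, with 75th percentiles of the signal of 521.8 to 677.8 against 412.8 to 488.7, so the split follows signal level; with slide as a block the real comparison gave 5 genes.

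The dimmer probe of each pair was not used in the comparisons and is given here because its signal changed against controls. By these probes 16 genes changed in D. montana acclimation, 2 at 15-min recovery, 6 at 1-hour recovery and 50 in D. virilis acclimation. Pairs of similar brightness, where the orientation could be assigned wrongly, are not the whole source, since 114 dimmer probes still changed in D. virilis acclimation with pairs over 1 log2 unit apart. Signal carried over from the brighter strand may account for part: 77.2% of changed dimmer probes in D. montana and 76.3% in D. virilis had the direction of their partner. The opposed 13 and 27 probes, which include probes of per in both species, keep this open, and antisense transcription was not tested.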

How the results depend on the processing

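The probe orientation choices, normexp without spots of outlying background and the slide block in list tests were chosen after seeing the data, and the other alternatives before; where no cause is named below, the cause was not tested. In the order D. montana acclimation, hardening, 15-min recovery, 1-hour recovery, D. virilis acclimation, D. virilis hardening, 1-hour against 15-min recovery, and the difference between species in acclimation and in hardening, the counts of changed genes were 57, 1, 14, 6, 83, 1, 4, 26 and 1. With normexp they were 11, 0, 1, 2, 16, 0, 1, 0 and 0, and the shared genes of acclimation in both species, of acclimation and 1-hour recovery and of both recovery times went from 33, 5 and 2 to 4, 2 and 1. On 4 arrays 2 to 10 spots had a background over 20 units above the spot, and there normexp moved the 75th percentile by 0.59 to 1.79 log2 units, against 0.06 to 0.17 elsewhere. Without those spots normexp gave counts within 1.5 times, except 9 at 15-min recovery and 7 between recovery times. Spike-in scaling gave 25 and 35 genes for acclimation in D. montana and D. virilis, 1 at 15-min recovery (0% higher), 4 for D. virilis hardening, and 4 and 2 for the differences between species in acclimation and hardening. Quantile normalization and the percentile over detected probes each gave 2 for D. virilis hardening and 2 for the difference in hardening, and 83.3% and 66.7% higher genes between recovery times against 100%. The median of all genes was -0.15 in D. montana hardening, -0.11 at 1-hour recovery and -0.16 for the difference in hardening with spike-in scaling, -0.12 at 1-hour recovery with quantile normalization and -0.11 in D. virilis acclimation with normexp.

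Fitting only the groups compared gave 0, 0 and 0 for both hardening comparisons and their difference, and 24 at 15-min recovery. A single fit of all 24 arrays gave 4 and 0 for D. montana and D. virilis hardening, 34 and 13 at 15-min and 1-hour recovery, and 9 between them. Array weights gave 95, 9, 31, 19, 12, 56 and 24 for D. montana acclimation, hardening, 15-min and 1-hour recovery, D. virilis hardening and the differences in acclimation and hardening. Slide as a block gave 30 and 14 at 15-min and 1-hour recovery and 4 for D. virilis hardening. Both probe orientations averaged gave 0 for D. virilis hardening and 0 for the difference in hardening. Other filters on dim probes, the brightest probe per gene and only pairs over 1 log2 unit apart kept every count within 1.5 times. The genes behind a count could still change. Of 20 named genes called for the difference in acclimation, 13 kept their call with the brightest probe. With both orientations averaged 14 did, and with spike-in scaling 4. Leaving out single arrays gave 34 to 45, 0 to 2, 1 to 30, 6 to 7, 58 to 95, 0 to 7, 4 to 5, 15 to 29 and 0 to 3 genes, and 22 to 33, 5 to 5 and 1 to 3 shared genes; a group then held 2 arrays.

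The replicate block gave 27 genes at 15-min recovery, 14 at 1-hour recovery, 4 in D. virilis hardening and 10 shared by both recovery times, and kept the other counts within 1.5 times. The numbers are those of the sample titles, and another label numbers the 1-hour recovery arrays differently, so the block and this check rest on the titles. Equal numbers did not pair the arrays: their deviations from group means correlated over 0.1 in 11 of 30 pairs in D. montana (mean r 0.051) and 4 of 9 in D. virilis (mean r 0.043), and 6 of 15 and 2 of 9 arrays correlated best with their own number.

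Of the named genes, Hsp67Bc turned to -0.25 and -0.10 in D. montana and D. virilis acclimation with the brightest probe, which is 1 of its 2 probes, and cwo to 0.060 in D. montana hardening. At 15-min recovery InR turned to 0.70 with normexp and 0.058 without the outlying spots, cac to 0.39 with normexp and 0.028 with no filter on dim probes, and sbb to 0.63 with normexp, 0.16 without the outlying spots and 0.43 with the brightest probe. In D. virilis acclimation ey turned to -0.027, per to -0.030 and cpo to -0.088 with normexp, per to -0.041 with the brightest probe and cac to 0.080 with no filter. Genes named in advance that did not pass had 61 values, of which 38 changed sign and 8 passed in an alternative. The authors' processed values, whose rows were matched by probe name order, gave 59, 1, 12, 6, 84, 2, 6, 35 and 2 changed genes in the order above, with 16.7% higher at 15-min recovery against 35.7% and 83.3% between recovery times against 100%. The median of all genes was then -0.12 at 1-hour recovery. No changed gene turned in direction with them, and their scale is linear, with no evident centring. Dim probes limit the measurement: pwn was not well above background on any acclimated D. montana array. Its lower mean there did not pass (adjusted p = 0.135), so the estimated bound of 1.30-fold lower is no evidence of a fall.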

Other observations

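The tests of the shared genes and of the probes in this part, and the genes of this paragraph, were chosen after the results were seen. Some genes outside the naming rule passed in acclimation of both species with 1 direction on every probe. The serotonin receptor gene 5-HT7 rose (0.64 ± 0.16 in D. montana and 0.56 ± 0.10 in D. virilis), as did the engulfment receptor gene drpr (0.57 ± 0.16 and 0.41 ± 0.14) and ken (0.47 ± 0.14 and 0.62 ± 0.10). The translesion polymerase gene Rev1 (-0.65 ± 0.13 and -0.35 ± 0.10), the postsynaptic scaffold gene homer (-0.44 ± 0.14 and -0.47 ± 0.11) and the tyrosine kinase gene Btk29A (-0.41 ± 0.14 and -0.45 ± 0.08) fell.

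The 4 genes that rose in D. montana both in acclimation and at 1-hour recovery, hsr-omega, Hsp68, stv and Thor, share 3 control arrays. In 2 comparisons with no array in common, acclimation against hardening and 1-hour against 15-min recovery, 3 of the 4 were higher in both: hsr-omega (2.70 ± 0.18 and 1.83 ± 0.18), Hsp68 (0.92 ± 0.15 and 1.25 ± 0.15) and stv (0.91 ± 0.13 and 0.82 ± 0.13). Chance values of the shared controls therefore do not account for these 3, while for Thor (0.41 ± 0.14 and 0.49 ± 0.14, adjusted p = 0.0427 and 0.0929) this stays open. The 1-hour against 15-min call of stv was lost with spike-in scaling, so for stv this depends on the scaling. With spike-in scaling 4 of the 4 passed against control both in acclimation and at 1-hour recovery, which argues against the 75th percentile as the source. A biological explanation, such as a response common to both treatments, was not tested and stays open.

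Probes of 1 gene disagreed in acclimation, and per is an example. Its 4 probes from pairs at least 3.35 log2 units apart changed by 1.06 to 1.18 in D. montana and 1.14 to 1.25 in D. virilis, while those from pairs at most 1.79 apart changed by -0.06 to 0.88 (5 probes) and -0.05 to -0.02 (3 probes). By their names the first 4 probes come from fragments numbered 2 or 4 and the others from fragments numbered 3. For per the gap and the fragment can therefore not be told apart. A candidate explanation is signal not specific to the gene where both orientations are about equally bright. Across changed genes, probes opposed to their gene made up 21.1% of 19 probes from pairs under 1 log2 unit apart and 2.09% of 191 from pairs over 4 apart in D. virilis (Fisher's exact test, two-sided, adjusted p = 0.00542), but 6.67% of 15 and 3.70% of 135 in D. montana (adjusted p = 0.475), so this is not settled. The gene per, which prompted this test, holds part of these probes; without it 2 of 17 and 4 of 188 probes were opposed in D. virilis (adjusted p = 0.160) and 0 of 11 and 5 of 132 in D. montana (adjusted p = 1), so neither species then passed. Transcript forms of per that respond unequally were not tested.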
